A study of Mus musculus with 6 samples.

How the data were processed

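Gene expression was measured in the left ventricle of 30-week-old chow-fed mice, 6 fl/fl and 6 CS-Mpc2-/-. Per the labels' protocols, RNA was taken from about 25 mg of frozen tissue, RNA of 2 hearts was pooled per library, ribosomal RNA was depleted, and total RNA libraries were sequenced on an Ion Torrent Proton. The 3 pools per group are separate animals. Samples were grouped by the genotype label and numbered by their titles.

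The deposited file holds 1 table. Its per-library values are a coverage signal that the authors scaled to nearly the same total in each library (261, in 1000000 units), as read from the values, since the labels do not state it. In each library at least 99.9917% of values were whole multiples of the library's smallest value (tolerance 0.01), and the next multiple above 1 was 21 to 47, so the units behave as aligned bases and not as reads. Counts of reads could not be recovered from them, and intervals for counting error are not given. The authors listed genes whose larger group mean was at least 700.158 in that unit, again as read from the values. The authors' table also gives the ratio of the group means and a p-value per gene, which equals an equal-variance test of the linear values to within 5.87e-09 and is unadjusted. The genome build is mm10, per the submitters' processing notes; the aligner, the counting step, the strand setting and the annotation are not given in the sources used here. Coverage of a gene and of an overlapping antisense gene can therefore not be told apart.

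The design fixed before the data were examined named tests for counts, for CPM, TPM or FPKM and for log2 values. It did not foresee a coverage signal, so the values were divided by the library total, expressed per 1000000 (ppm), and given the test written for such units. They were transformed as log2(value + 1 ppm), so fold changes of low genes are understated. Genes with a mean of at least 1 ppm were kept, a filter that removed 0 of the 12072 genes because the lowest mean was 1.54. Groups were compared by limma 3.58.1 (lmFit, eBayes with an intensity trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The model had the group as its only term. Gene lists were tested by limma's camera with a correlation of 0.01, with an estimated correlation, and by fry, with adjustment over the 28 lists that had at least 4 measured members, and per gene over all genes and over each list alone. The lists of structural RNAs and sex-linked genes were described only. Mpc2 was left out of its own list in the set test. Single values were compared by an exact permutation test of 3 against 3, which has 20 arrangements and cannot go below 0.1.

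Genes were named by a rule fixed before the data were examined: Mpc2 and Mpc1; the 10 largest rises and 10 largest falls among genes past the threshold with no overlap between groups and a mean of at least 2 ppm, predicted genes skipped; up to 4 members per list past the threshold; and otherwise the 2 members with the smallest unadjusted p, as values. With all 6 libraries no gene passed, so the rule for the largest changes was applied to the fit without fl/fl replicate 3. That step, and the naming of Nppa, Nppb and Ankrd1 ahead of it and of Xirp2, Ctgf, Gdf15, Fhl1, Enah, Myh6, Myh7, Myh7b, Postn, Timp1, Pdk2, Pdk4, Pdp2, Me2, Ppp1r3c, Gbe1, Pfkp, Ppara, Ppargc1a, Cpt2, Atp2a2, Ryr2, Kcnj2, Kcnd2, Atf4, Asns, Junb, Dkk3, Pam, Tbx5, Sfrp1, Prelp, Igf1 and Vaultrc5, were chosen after the values were seen. A few genes that the rule names are not reported here.

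On simulated data with the spread of these libraries, the limma step run on 12072 genes recovered 32% of 100 genes changed 2-fold and 84% of 100 changed 4-fold with 3 against 3 libraries, and 24% and 69% with 2 against 3, with 4 false calls each. The changed genes were picked at random among those with a mean of at least 2 ppm, each with its own spread. These rates therefore do not hold for genes that vary widely within a group, such as Nppa (SE of 1.05 on the log2 scale). Camera called the 1 list that was moved and 0 others. In these simulations genes were drawn independently of each other. Members of the real lists are correlated (up to 0.70, estimated for the matrix list), so the 0 others says nothing about false calls in these data. Alternatives fixed beforehand were upper quartile scaling, limma without the trend, no filter, a mean of at least 5 ppm, pseudocounts of 0.1 and 5, robust estimation, the replicate number as a block, and each library left out in turn. Added after the data were seen were replicate 3 of both groups left out, limma array weights, median-of-ratios scaling, a pseudocount of 1 in the deposited unit, rescaling without small RNA genes and removal of each library's transcript length trend. Gene positions and transcript lengths came from GENCODE M21 on mm10 coordinates and covered 99.4% of genes.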

Results

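Left ventricular RNA was measured in 30-week-old mice on a chow diet, from hearts of fl/fl animals, whose Mpc2 gene carries recombination sites, and of CS-Mpc2-/- animals, in which Mpc2 is deleted in the heart. The comparison asks how the ventricular transcriptome differs when the mitochondrial pyruvate carrier is lost, in a study of glycogen storage and heart failure. There were 6 mice per group, and RNA of 2 hearts was pooled for each library, giving 3 libraries per group. Each library is a separate pool of animals. The authors' table lists 12072 genes with a read coverage value in every library, here expressed per 1000000 units of the library total (ppm). The coverage behind these values, in 1000000 of the smallest steps of each library, was 92.9, 202 and 389 for fl/fl replicates 1, 2 and 3, and 287, 319 and 278 for CS-Mpc2-/- replicates 1, 2 and 3. The shallowest libraries were therefore fl/fl replicates 1 and 2.

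Mpc2, a subunit of the carrier that brings pyruvate into mitochondria, was lower in 2 of the 3 CS-Mpc2-/- libraries than in every fl/fl library and was at the fl/fl level in the other. It was at 45.2, 38.9 and 27.7 ppm in fl/fl replicates 1, 2 and 3, and at 14.9 and 18.2 ppm in CS-Mpc2-/- replicates 1 and 2. The library labelled CS-Mpc2-/- replicate 3 had 46.3 ppm, 1.24 times the fl/fl mean, while replicates 1 and 2 had a mean of 16.5, or 44.3% of the fl/fl mean. Mpc2 (ENSMUSG00000026568.6) lies on chromosome 1 from 165460637 to 165481214 of mm10, on the plus strand. Its longest coding transcript has 5 exons, and 0 other annotated genes overlap those of the gene. The value covers the whole gene and does not separate deleted from remaining exons. The group means were 37.3 ± 8.87 and 26.5 ± 17.3 ppm (SD, n = 3 each), a difference smaller than the spread within the CS-Mpc2-/- group. On the log2 scale the difference was -0.63 ± 0.35 (SE), with a Benjamini-Hochberg adjusted p of 0.453 in limma. An exact permutation test of the 3 and 3 values gave a two-sided p = 0.4, where 0.1 is the smallest possible. Without the library labelled CS-Mpc2-/- replicate 3 the log2 difference was -1.11, with an adjusted p of 0.196 in limma (0.00279 to 0.818 over all alternatives).

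Mpc1, the partner subunit, lies on chromosome 17 from 8282904 to 8297661 and was higher in each of the 3 CS-Mpc2-/- libraries than in any fl/fl library. Its means were 85.3 ± 16.0 and 117 ± 20.1 ppm (SD, n = 3 each), and the log2 difference was 0.46 ± 0.20 (SE). That difference did not pass the test over all genes (limma adjusted p = 0.347), and the exact permutation p was 0.1, the smallest possible. The Mpc1 transcript has 961 nt. Genes of 700 to 1000 nt stood at -0.18, -0.13 and 0.03 in fl/fl and at 0.09, 0.05 and 0.17 in CS-Mpc2-/- on the log2 scale. Length and genotype were not separated for this gene.

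**Figure D1:**
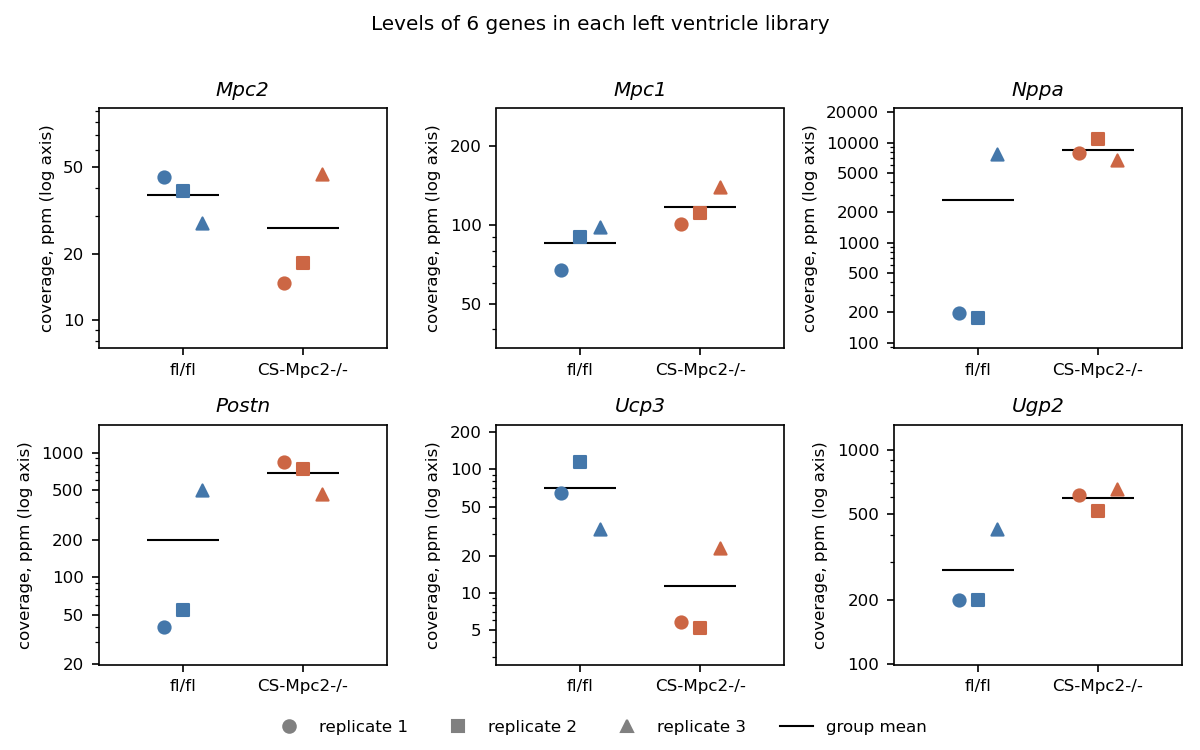
Coverage in ppm (log axis) of Mpc2, Mpc1, Nppa, Postn, Ucp3 and Ugp2 in each of the 6 libraries, with fl/fl in blue, CS-Mpc2-/- in orange, a marker shape per replicate number and a line at the group mean. The library labelled CS-Mpc2-/- replicate 3 had Mpc2 at 46.3 ppm, and fl/fl replicate 3 had Nppa at 7656 ppm, near the 6696 to 10961 of the CS-Mpc2-/- libraries.

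Nppa, Nppb and Ankrd1, chosen after their values were seen, were higher in the CS-Mpc2-/- libraries than in fl/fl replicates 1 and 2. In fl/fl replicate 3 they lay near or among the CS-Mpc2-/- values, and with all 6 libraries none of the 3 passed (limma adjusted p = 0.220 for each). Nppa, which encodes atrial natriuretic peptide, was at 197, 175 and 7656 ppm in fl/fl and at 7834, 10961 and 6696 in CS-Mpc2-/-. Nppb, which encodes B-type natriuretic peptide, was at 52.9, 44.2 and 952 in fl/fl and at 1204, 1378 and 1303 in CS-Mpc2-/-. Ankrd1, a stretch-responsive protein of the sarcomere, was at 359, 293 and 2152 against 2957, 3426 and 2402 ppm. With all 6 libraries, limma found 0 genes higher and 0 lower at an adjusted p under 0.05, with 0.220 as the smallest adjusted p. At an unadjusted p under 0.05 there were 1631 genes, 975 higher and 656 lower, where chance alone would give 603.6 on average. The 3 CS-Mpc2-/- values lay wholly above or below the 3 fl/fl values for 1749 genes, 14.5% of those listed, against 10% on average by chance. Genes are correlated, so single counts can lie far from such averages. Other splits of the 6 libraries into 3 and 3 gave 73 to 1645 genes at that unadjusted threshold, so the excess cannot be credited to genotype.

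Leaving out fl/fl replicate 3, which is 1 of the 6 planned fits that each drop a library, gave 786 genes higher and 531 lower in CS-Mpc2-/- (limma, adjusted p under 0.05), of which 512 and 267 differed at least 2-fold. Each of the other 5 such fits gave 0 and 0. Over these 1317 genes fl/fl replicate 3 lay at a median of 0.828 of the way from the mean of fl/fl replicates 1 and 2 to the CS-Mpc2-/- mean on the log2 scale, and it was nearer CS-Mpc2-/- for 1229 of them (93.3%). The first principal component, with 54.6% of the variance, placed fl/fl replicates 1 and 2 at -47.8 and -42.3, fl/fl replicate 3 at 14.8, and the CS-Mpc2-/- libraries at 30.8, 26.4 and 18.1. The library labelled CS-Mpc2-/- replicate 3, whose Mpc2 goes against its label, stays in the CS-Mpc2-/- group of every direction given here; without replicate 3 of both groups, a choice made after the data were examined, 874 genes were higher and 640 lower, and 1134 of these were among the 1317.

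**Figure D2:**
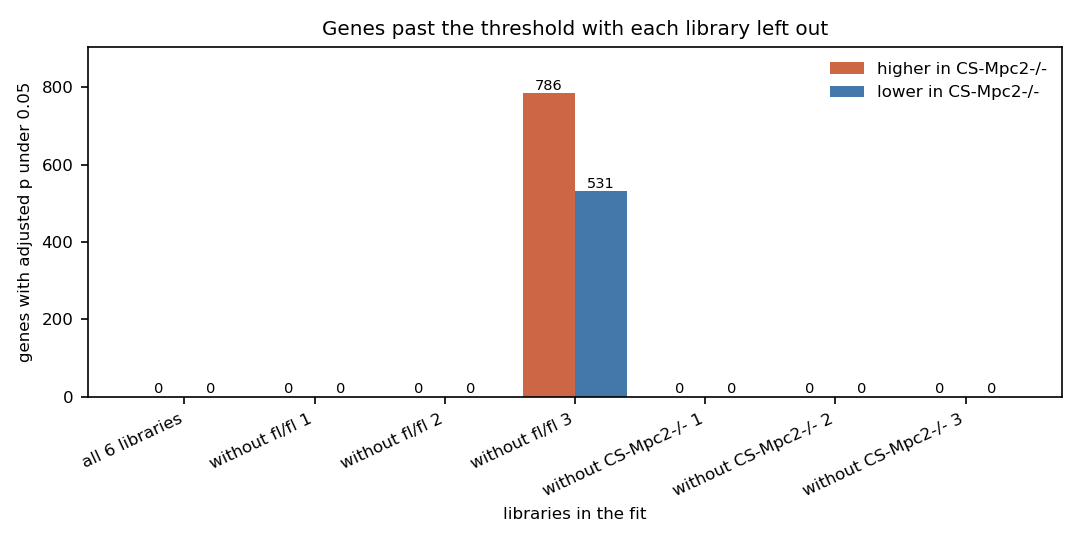
Number of genes with a limma adjusted p under 0.05 (bars, y axis) in the fit of all 6 libraries and in the 6 fits that leave out 1 library each (x axis), higher in CS-Mpc2-/- in orange and lower in blue. Only the fit without fl/fl replicate 3 gave any, 786 higher and 531 lower.

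With fl/fl replicate 3 left out, the 10 largest rises were in Nmrk2, a kinase that makes an NAD precursor, Wisp2, a matricellular protein, Thbs4, a thrombospondin, Nppa, Ltbp2, a protein of elastic microfibrils, Lox, which cross-links collagen, Comp and Cilp, both cartilage-type matrix proteins, Nppb and the fibril-associated collagen Col12a1. The CS-Mpc2-/- mean of 9 of these genes was 26.7 to 120 times the mean of fl/fl replicates 1 and 2, but 3.18 to 4.91 times the mean of all 3 fl/fl libraries. Lox is left out of these ratios because fl/fl replicate 1 had no coverage of it above the smallest step. The top ratios, 120 for Nmrk2 and 110 for Wisp2, rest on 0.559 to 2.42 ppm in fl/fl replicates 1 and 2. Those are the shallowest libraries, so these ratios are imprecise. Nmrk2 rose most, by 6.07 ± 0.46 (SE) on the log2 scale, from 2.42 and 0.559 ppm in fl/fl replicates 1 and 2 to 259, 208 and 68.0 in CS-Mpc2-/-, and fl/fl replicate 3 had 149. The adjusted p of the 10 genes was 7.72e-10 to 2.38e-06 in that limma fit, 0.220 to 0.239 with all 6 libraries, and 2.82e-10 to 0.769 over all alternatives.

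The 10 largest falls without fl/fl replicate 3 included Ucp3, a mitochondrial uncoupling protein tied to fatty acid use, Ces1d, a carboxylesterase that acts on lipid esters, Kcnv2, a potassium channel subunit, and Slc22a3, an organic cation transporter. The others were Col6a6, Tmem82, Efnb3, Lgals6, Klhl33 and Cenpf. Ucp3 fell by 3.11 ± 0.46 (SE) on the log2 scale, with 64.3 and 114 ppm in fl/fl replicates 1 and 2, 32.8 in fl/fl replicate 3, and 5.80, 5.20 and 23.1 in CS-Mpc2-/-. The mean of fl/fl replicates 1 and 2 was 3.93 to 8.65 times the CS-Mpc2-/- mean for these genes, and that of all 3 fl/fl libraries 3.21 to 6.73 times. The library labelled CS-Mpc2-/- replicate 3 was above fl/fl replicate 3 for Ces1d, Kcnv2, Efnb3, Klhl33 and Cenpf, and below it for the others. The adjusted p of the 10 genes was 0.00018 to 0.0222 in that limma fit, 0.220 to 0.223 with all 6 libraries, and 5.68e-07 to 0.769 over all alternatives. Lgals6 has a near-identical neighbour, Lgals4, and coverage of such copies can be split between them, so its level is uncertain.

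Of 35 gene lists fixed before the data were examined, 28 had at least 4 measured members and were tested with all 6 libraries. Limma's camera, with a preset correlation of 0.01 between genes, called 7 lists higher and 5 lower in CS-Mpc2-/-. With a correlation estimated from the data 0 were called (smallest adjusted p = 0.466 with an estimated correlation), and fry, which asks whether a list moves on balance one way, called 0 (smallest adjusted p = 0.204). In each list below, 0 members passed the test adjusted over all genes with all 6 libraries. The counts adjusted over a list alone depended on the libraries and on limma's settings. Without limma's intensity trend 0 members were lower in the fatty acid, calcium and pyruvate lists, and with robust estimation 6 were higher in the matrix list and 2 in the hypertrophy list. Without the trend 0 were higher or lower in the glycolysis, ketone body, ribosomal and smooth muscle lists.

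The hypertrophy and fetal gene list was called higher, with a median log2 difference of 0.80 over 22 members (camera adjusted p = 0.000444; adjusted p = 0.466 with an estimated correlation), which was 0.45 without fl/fl replicate 1 and 1.10 without fl/fl replicate 3. Adjusted over the list alone, 10 members were higher and 1, Myh7b, was lower, and with 1 library left out 8 to 14 were higher and 0 or 1 lower. Acta1, the skeletal actin of the fetal heart, rose by this test from 46.1 ± 21.6 to 132 ± 8.33 ppm (SD, n = 3 each), a log2 difference of 1.61 ± 0.28 (SE). Rcan1, a calcineurin target, rose by 1.67 ± 0.37, Xirp2, an actin-binding protein of the intercalated disc, by 1.45 ± 0.42, Ctgf, a matricellular growth factor, by 2.13 ± 0.55, and Gdf15, a secreted stress signal, by 2.10 ± 0.59. Gdf15 had no coverage above the smallest step in fl/fl replicate 2 and 1.52 ppm in fl/fl replicate 1. Nppa, Nppb, Ankrd1, Fhl1 and Enah completed the 10. Myh7, the slow myosin heavy chain, was not among them, at 15352 ± 2233 in fl/fl and 13952 ± 4598 in CS-Mpc2-/-. Its coverage was not low in any library (10780 to 19225.5 ppm). How coverage was assigned between Myh7 and Myh6 is unknown, since the aligner is not given. Myh6, the adult fast chain on the sarcomere list, was at 65413, 66012 and 30974 ppm in fl/fl and at 37522, 40319 and 33936 in CS-Mpc2-/-.

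Genes of the extracellular matrix and fibrosis moved most as a group. The list had a median log2 difference of 1.40 over 40 members, 39 of them positive (camera adjusted p = 7.35e-18; adjusted p = 0.466 with an estimated correlation), and 36 were higher and 0 lower adjusted over the list alone (26 to 37 higher with 1 library left out). Postn, a protein of activated fibroblasts, was at 39.4, 53.9 and 502 ppm in fl/fl and at 834, 744 and 465 in CS-Mpc2-/-. Fbn1, the fibrillin of microfibrils, rose over the list alone by 1.38 ± 0.32 (SE) on the log2 scale, Meox1, a transcription factor of activated fibroblasts, by 1.83 ± 0.42, and Timp1, a metalloproteinase inhibitor, by 2.80 ± 0.80, with 134 ppm in CS-Mpc2-/- replicate 1 against 15.1 and 10.1 in the others. Fibroblast markers were called higher too, with a median of 0.57 over 12 members (camera adjusted p = 0.00323; adjusted p = 0.466 with an estimated correlation), and 5 were higher and 0 lower adjusted over the list alone (2 higher without fl/fl replicate 2, 3 without fl/fl replicate 1 and 6 without fl/fl replicate 3). Among these were Pi16, a secreted protein of fibroblasts (1.23 ± 0.29), and the collagen gene Col1a1 (1.81 ± 0.43), which the matrix list also holds.

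Macrophage markers had a median log2 difference of 0.41 over 13 members (camera adjusted p = 0.0210; adjusted p = 0.466 with an estimated correlation), with 0 higher and 0 lower adjusted over the list alone (3 and 1 without fl/fl replicate 3). The complement genes C1qa and C1qb had log2 differences of 0.78 ± 0.26 and 0.68 ± 0.26 (SE). Without fl/fl replicate 1 or without CS-Mpc2-/- replicate 1 this list was not called (camera adjusted p = 0.0560 and 0.0965, and 0.00625 to 0.0965 over all alternatives), nor without replicate 3 of both groups (0.0636). Immediate early genes were called higher, with a median of 0.45 over 18 members (camera adjusted p = 0.000661; adjusted p = 0.466 with an estimated correlation). Its median was 0.22 without CS-Mpc2-/- replicate 1, and camera still called the list (adjusted p = 0.0210, and 5.48e-06 to 0.0210 over all alternatives). Adjusted over the list alone 3 were higher and 0 lower, namely Btg2, Egr2 and Junb, with 1 higher without CS-Mpc2-/- replicate 1 and 5 without replicate 3 of either group. Egr2 had no coverage above the smallest step in fl/fl replicates 1 and 2. The median of this list relative to all libraries was 0.54 and 0.14 in CS-Mpc2-/- replicates 1 and 2, but -0.10 in the library labelled CS-Mpc2-/- replicate 3 and -0.07 in fl/fl replicate 3. The antiproliferative gene Btg2 was at 53.2, 52.0 and 74.3 ppm in fl/fl and at 167, 123 and 97.8 in CS-Mpc2-/-. The inflammation and interferon list was not called (median 0.12, 0.07 to 0.21 with 1 library left out, camera adjusted p = 0.318), while 2 of its 18 members, the complement gene C4b and the protease inhibitor Serpina3n, were higher and 0 lower adjusted over the list alone. These counts were 5 and 1 without fl/fl replicate 3, and 0 and 0 when any library numbered 1 or 2 was left out. They were also 0 and 0 without limma's intensity trend and with robust estimation.

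Fatty acid uptake and oxidation was the list with the most members lower. Its median log2 difference was -0.59 over 31 members, 30 of them negative (camera adjusted p = 1.23e-13; adjusted p = 0.466 with an estimated correlation), and 16 were lower and 0 higher adjusted over the list alone. That count was 20 without fl/fl replicate 3, but 1 when any library numbered 1 or 2 was left out. By that test with all 6 libraries Acaa2, the thiolase of the last step of beta-oxidation, fell by 1.13 ± 0.28 (SE) on the log2 scale, and Cpt2, which releases acyl groups from carnitine inside mitochondria, fell by 1.09 ± 0.29. Ppara, a nuclear receptor for fatty acids, fell by 0.61 ± 0.16, and Ppargc1a, its coactivator, fell by 0.97 ± 0.28. Ucp3 was also among the 16, with a log2 difference of -2.66 ± 0.50. The list's median relative to all libraries was -0.37 and -0.38 in CS-Mpc2-/- replicates 1 and 2 but -0.06 in the library labelled CS-Mpc2-/- replicate 3, and -0.00 in fl/fl replicate 3. Without fl/fl replicate 3, 17 of the 31 were lower in the test over all genes.

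The TCA cycle list was called lower, with a median log2 difference of -0.28 over 18 members (camera adjusted p = 0.000661; adjusted p = 0.466 with an estimated correlation) and 0 higher or lower adjusted over the list alone, against 6 lower without fl/fl replicate 3 and 4 of them over all genes. Citrate synthase, Cs, had a difference of -0.51 ± 0.19 and the succinate dehydrogenase subunit Sdha -0.49 ± 0.19 (SE). Amino acid and branched-chain amino acid catabolism was called lower as well, with a median of -0.30 over 22 members (camera adjusted p = 0.000241; adjusted p = 0.466 with an estimated correlation) and 0 higher or lower adjusted over the list alone, against 7 lower without fl/fl replicate 3 (5 over all genes) and 8 without the library labelled CS-Mpc2-/- replicate 3. Its smallest unadjusted p-values belonged to Ppm1k, the phosphatase that activates the branched-chain ketoacid dehydrogenase (-1.06 ± 0.32), and Ivd, isovaleryl-CoA dehydrogenase (-0.65 ± 0.20). Relative to the mean of all libraries, the median of the amino acid list was 0.24 and 0.25 in fl/fl replicates 1 and 2, -0.23 and -0.24 in CS-Mpc2-/- replicates 1 and 2, 0.01 in fl/fl replicate 3 and 0.09 in the library labelled CS-Mpc2-/- replicate 3, which stood apart from its group. For the TCA cycle list the libraries numbered 3 were at -0.00 and -0.01. Ketone body metabolism was not called (median -0.37, camera adjusted p = 0.0886), and 1 of its 7 members, the mitochondrial acetate-activating enzyme Acss1, was lower and 0 higher adjusted over the list alone (3 lower and 1 higher without fl/fl replicate 3, and 0 when any library numbered 1 or 2 was left out). The thiolase Acat1 was at -0.48 ± 0.17. The nuclear-encoded respiratory chain had a median of -0.01 over 48 members (-0.10 to 0.07 with 1 library left out, camera adjusted p = 0.465), with 0 higher or lower adjusted over the list alone (4 and 3 without fl/fl replicate 3). Its mean was 0.01, opposite in sign to the median, and Ndufa10 and Cox6a2, subunits of complexes I and IV, had differences of -0.58 ± 0.20 and -0.67 ± 0.24.

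Genes of pyruvate transport and use went both ways. The list without Mpc2 was not called (median -0.11 over 22 members, -0.20 to -0.05 with 1 library left out, camera adjusted p = 0.195), and adjusted over the list alone 1 member was higher and 5 were lower. These counts were 7 and 7 without fl/fl replicate 3 (3 and 6 over all genes). They were 0 and 4 without the library labelled CS-Mpc2-/- replicate 3, and 0 and 0 when any library numbered 1 or 2 was left out. Of the kinases that inhibit pyruvate dehydrogenase, Pdk2 fell by 1.08 ± 0.29 (SE) on the log2 scale and Pdk4 fell by 1.20 ± 0.38, and Pdp2, a phosphatase that activates it, fell by 1.43 ± 0.40. Gpt2 and Gpt, the aminotransferases that interconvert alanine and pyruvate in mitochondria and cytosol, had log2 differences of -1.12 ± 0.29 and -1.04 ± 0.28 and also fell by this test, and the malic enzyme Me2 rose by 1.05 ± 0.35. Pdk4 was at 372, 566 and 213 ppm in fl/fl and at 102, 126 and 285 in CS-Mpc2-/-, the last being the library labelled CS-Mpc2-/- replicate 3.

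Glycogen metabolism was not called as a list (median 0.07 over 24 members, -0.04 to 0.16 with 1 library left out, camera adjusted p = 0.638), with 2 members higher and 1 lower adjusted over the list alone. The counts were 0 and 0 without fl/fl replicate 1, fl/fl replicate 2 or CS-Mpc2-/- replicate 1, and 1 and 0 without CS-Mpc2-/- replicate 2. They were 1 and 2 without the library labelled CS-Mpc2-/- replicate 3, and 3 and 1 without fl/fl replicate 3. Without limma's intensity trend the counts were 0 and 0, and with robust estimation 1 and 1. With all 6 libraries Ugp2, which makes the UDP-glucose that glycogen synthase uses, rose by this test from 274 ± 131 to 596 ± 69.2 ppm (SD, n = 3 each), with a log2 difference of 1.21 ± 0.26 (SE). Ppp1r3c, which targets a phosphatase to glycogen, rose by 1.24 ± 0.33, and Phkg1, a catalytic subunit of phosphorylase kinase, fell by 1.60 ± 0.40. The branching enzyme Gbe1 had a difference of 0.75 ± 0.25, which did not pass. Glycolysis was not called (median 0.10 over 19 members, -0.05 to 0.19 with 1 library left out, camera adjusted p = 0.791). The members higher and lower adjusted over the list alone numbered 7 and 3 without fl/fl replicate 3 (4 and 2 over all genes), and 0 and 0 when any library numbered 1 or 2 was left out. Adjusted over the list alone with all 6 libraries, 0 were higher and 1 lower, the kinase Pfkfb1 that sets fructose 2,6-bisphosphate, at -1.91 ± 0.49, while Pgam1, a phosphoglycerate mutase, had 0.86 ± 0.27 and Pfkp, a phosphofructokinase, 1.22 ± 0.40. The pentose phosphate and hexosamine list was not called (median 0.17 over 14 members, 0.11 to 0.26 with 1 library left out, camera adjusted p = 0.124), with 0 higher or lower adjusted over the list alone (3 higher without fl/fl replicate 3). Gfpt1, the entry enzyme of hexosamine synthesis, and the transketolase Tkt had differences of 0.47 ± 0.21 and 0.52 ± 0.23.

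**Figure D3:**
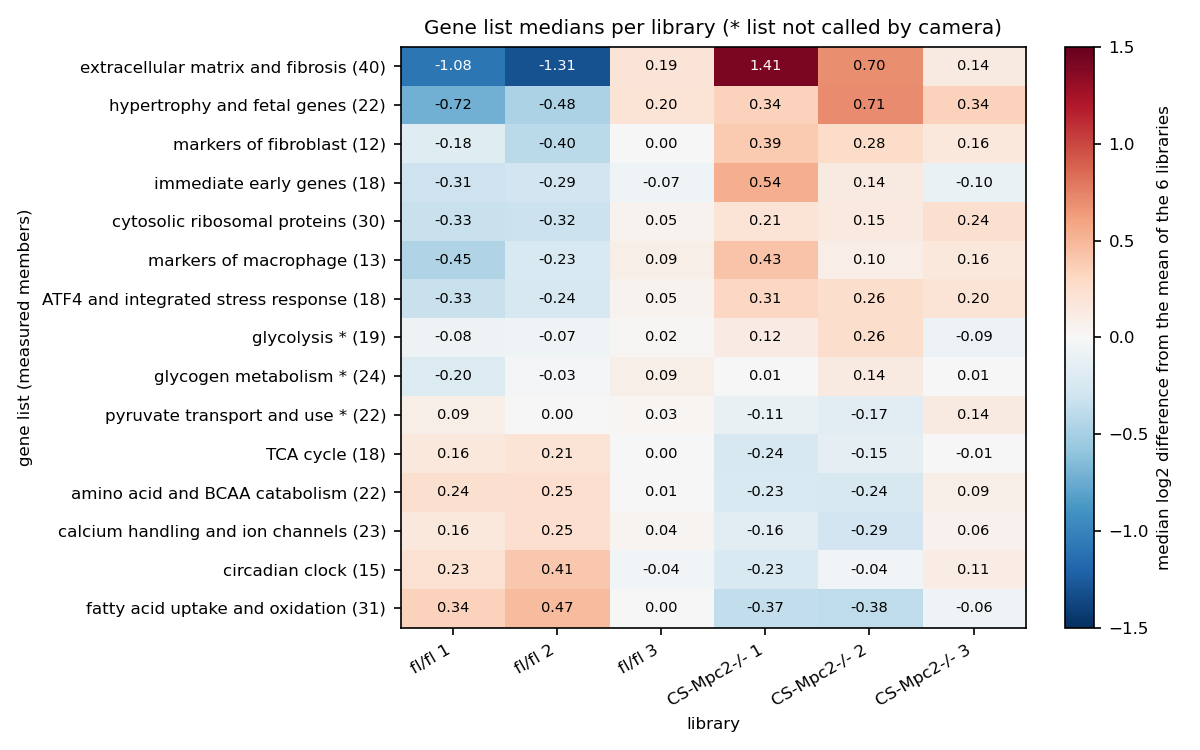
Median log2 difference from the mean of the 6 libraries (colour and printed value) of each gene list (rows, with the number of measured members) in each library (columns), for the 12 lists called by camera and for glycolysis, glycogen and pyruvate genes, which were not called. In the matrix list fl/fl replicates 1 and 2 were at -1.08 and -1.31, fl/fl replicate 3 at 0.19, and the CS-Mpc2-/- libraries at 1.41, 0.70 and 0.14.

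Calcium handling and ion channel genes were called lower, with a median log2 difference of -0.30 over 23 members (camera adjusted p = 0.000371; adjusted p = 0.466 with an estimated correlation), and 10 were lower and 0 higher adjusted over the list alone. The number lower was 0 without fl/fl replicate 1, fl/fl replicate 2 or CS-Mpc2-/- replicate 2, and 1 without CS-Mpc2-/- replicate 1. Leaving out fl/fl replicate 3 gave 10 lower and 2 higher. Atp2a2, the calcium pump of the sarcoplasmic reticulum, was at 6112, 6514 and 3659 ppm in fl/fl and at 2785, 2225 and 4086 in CS-Mpc2-/-, and its log2 difference was -0.84 ± 0.29 (SE). Ryr2, the calcium release channel, fell over the list alone by 0.63 ± 0.24, and Hrc, a calcium-binding protein of the reticulum, fell by 1.20 ± 0.32. The potassium channel genes Kcnj2, Kcnd2 and Kcnv2 also fell, with differences of -1.19 ± 0.32, -1.06 ± 0.35 and -1.91 ± 0.50. The calcium list's median relative to all libraries was -0.16 and -0.29 in CS-Mpc2-/- replicates 1 and 2, but 0.06 in the library labelled CS-Mpc2-/- replicate 3 and 0.04 in fl/fl replicate 3. The sarcomere list was not called (median -0.07 over 19 members, -0.05 to 0.02 with 1 library left out, camera adjusted p = 0.561), with 0 higher or lower adjusted over the list alone (3 and 4 without fl/fl replicate 3, 0 and 1 without the library labelled CS-Mpc2-/- replicate 3). Tcap, the titin cap, was at -0.81 ± 0.24 and Pdlim5, a Z-disc protein, at 0.68 ± 0.26. Circadian clock genes were called lower, with a median of -0.47 over 15 members (camera adjusted p = 0.0158; adjusted p = 0.466 with an estimated correlation) and 0 higher or lower adjusted over the list alone, against 7 lower without fl/fl replicate 3 (3 over all genes) and 5 without the library labelled CS-Mpc2-/- replicate 3. Per3, a repressor of the clock, had -0.83 ± 0.24 and its output factor Hlf -1.04 ± 0.37. The clock list's median was -0.04 in fl/fl replicate 3 and 0.11 in the library labelled CS-Mpc2-/- replicate 3, against -0.23 and -0.04 in CS-Mpc2-/- replicates 1 and 2. Without fl/fl replicate 1 or CS-Mpc2-/- replicate 1 the clock list was not called (camera adjusted p = 0.0825 and 0.0692, and 0.00142 to 0.0825 over all alternatives).

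Cytosolic ribosomal protein genes were called higher, with a median log2 difference of 0.42 over 30 members, 29 of them positive (camera adjusted p = 1.22e-05; adjusted p = 0.466 with an estimated correlation). Adjusted over the list alone 1 was higher, Rpl3 at 1.06 ± 0.23 (SE), and 0 were lower. The number higher was 12 without fl/fl replicate 3 (9 over all genes), and 0 when any library numbered 1 or 2 was left out. Many of these genes have processed pseudogenes, so their coverage is uncertain, and short transcripts as a class were lower in fl/fl replicates 1 and 2. The ATF4 and integrated stress response list was called higher, with a median of 0.28 over 18 members (camera adjusted p = 0.0434; adjusted p = 0.593 with an estimated correlation), and 1 was higher and 0 lower adjusted over the list alone, against 7 without fl/fl replicate 3 and 0 when any other library was left out. The list's median was 0.44 without the library labelled CS-Mpc2-/- replicate 3. The member was Mthfd2, a mitochondrial folate enzyme, at 1.18, 3.10 and 5.48 ppm in fl/fl and at 10.8, 8.49 and 12.3 in CS-Mpc2-/-. Aldh18a1, which starts proline synthesis, had a difference of 0.87 ± 0.26, the factor Atf4 itself 0.68 ± 0.26 (1.03 without fl/fl replicate 3), and asparagine synthetase, Asns, 1.05 ± 0.41. Without fl/fl replicate 1, CS-Mpc2-/- replicate 1 or CS-Mpc2-/- replicate 2 the ATF4 list was not called (camera adjusted p = 0.135, 0.0952 and 0.0787, and 0.00950 to 0.135 over all alternatives), nor with a pseudocount of 0.1 ppm or of 1 in the deposited unit (0.0576 and 0.0593). The NRF2 and antioxidant list (median 0.25 over 23 members, 0.11 to 0.26 with 1 library left out, camera adjusted p = 0.334) and the lysosome and autophagy list (median 0.22 over 25 members, 0.12 to 0.30 with 1 library left out, camera adjusted p = 0.154) were not called, and each had 0 higher or lower adjusted over the list alone. Leaving out fl/fl replicate 3 gave 4 higher in the NRF2 list, and 5 higher and 1 lower in the lysosome list. Leaving out the library labelled CS-Mpc2-/- replicate 3 gave 1 higher in the NRF2 list. Their smallest unadjusted p-values belonged to Hmox1 (1.35 ± 0.38), heme oxygenase, and Gpx1 (0.82 ± 0.28), a glutathione peroxidase, and to the cathepsins Ctsa (0.49 ± 0.18) and Ctsd (0.54 ± 0.22).

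Markers of other cell types were not called for endothelium (median log2 difference 0.12 over 14 members, camera adjusted p = 0.410), smooth muscle and pericytes (-0.06 over 13, 0.419), atrial myocytes (0.14 over 8, 0.778), erythroid cells (-0.19 over 6, 0.251), skeletal muscle (-0.48 over 6, 0.318) or mesothelium and epicardium (0.85 over 6, 0.110). With 1 library left out these medians ran from 0.07 to 0.22 for endothelial, -0.09 to 0.01 for smooth muscle, -0.09 to 0.28 for atrial, -0.38 to 0.01 for erythroid, -1.06 to 0.00 for skeletal muscle and 0.47 to 1.38 for mesothelial markers. The upper ends for atrial and mesothelial markers and the lower end for skeletal muscle markers were those without fl/fl replicate 3. Adjusted over the list alone, the counts higher and lower were 0 and 0 for endothelial, erythroid and mesothelial markers, 1 and 1 for smooth muscle, 3 and 3 for atrial and 1 and 0 for skeletal muscle markers. Leaving out fl/fl replicate 3 gave 3 and 0 for endothelial, 4 and 0 for mesothelial, 1 and 2 for smooth muscle and 1 and 5 for skeletal muscle markers. Leaving out the library labelled CS-Mpc2-/- replicate 3 gave 1 and 0 for mesothelial and 1 and 1 for skeletal muscle markers. When any library numbered 1 or 2 was left out, the smooth muscle counts were 0 and 0. Camera called skeletal muscle markers lower without fl/fl replicate 3 (adjusted p = 0.0281, and 0.0281 to 0.935 over all alternatives; adjusted p = 0.464 with an estimated correlation). Without the library labelled CS-Mpc2-/- replicate 3 it called mesothelial markers higher (0.00696, range 0.00353 to 0.360), and erythroid markers (0.0349, range 0.0349 to 0.942) and ketone body genes (0.0370, range 0.0370 to 0.165) lower. These 3 calls were lost as well, with adjusted p = 0.324 with an estimated correlation for mesothelial markers and for ketone body genes, and adjusted p = 0.448 with an estimated correlation for erythroid markers. The atrial list had a positive median and mean but a negative direction in camera. The endothelial genes Vwf and Fabp4 had differences of 0.46 ± 0.21 and 0.43 ± 0.22 (SE), and the smooth muscle genes Tagln, a contractile protein, and Abcc9, a potassium channel subunit that myocytes also express, 0.74 ± 0.22 and -0.96 ± 0.24. The 6 atrial markers past the list-alone test were Nppa, Dkk3 and Pam, which were higher, and Kcnj3, Stard10 and Tbx5, which were lower. Slc4a1 of the erythroid list was at -0.46 ± 0.36, Casq1 of the skeletal list at -1.01 ± 0.39, and the keratins Krt19 and Krt8 of the mesothelial list at 1.57 ± 0.61 and 1.31 ± 0.59. Both keratins had no coverage above the smallest step in fl/fl replicates 1 and 2. In CS-Mpc2-/- replicates 1, 2 and 3 Krt19 was at 7.31, 3.38 and 1.02 ppm and Krt8 at 5.81, 1.45 and 0.897, against 1.75 and 1.04 in fl/fl replicate 3. Of the remaining 7 lists 6 had fewer than 4 measured members, among them the mitochondrially encoded respiratory chain and lymphocyte markers with 0, and the structural RNA list was only described. In these lists 0 members were higher adjusted over the list alone and 1, Kcna1, was lower. Leaving out fl/fl replicate 3 gave 1 higher and 1 lower for Schwann cell genes, 1 higher for structural RNAs and 1 lower for adipocyte genes, and leaving out the library labelled CS-Mpc2-/- replicate 3 gave 1 higher and 1 lower for Schwann cell genes. The granulocyte genes Csf3r and S100a9 were at 0.82 ± 0.50 and 0.63 ± 0.58, the adipocyte genes Lipe and Cidea at -0.60 ± 0.24 and -0.14 ± 0.28, the Schwann cell list genes Kcna1 and Ncam1 at -1.20 ± 0.30 and 1.56 ± 0.70, the structural RNAs Rpph1 and Rmrp at 0.94 ± 0.33 and 0.40 ± 0.21, and Xist at 0.12 ± 0.22. Without fl/fl replicate 3 the log2 difference was 2.44 for Ncam1, -0.75 for Slc4a1 and 0.65 for Fabp4. Xist was at 149 to 269 ppm across the libraries. Of the 6 sex-linked genes the authors listed Xist alone and none of the Y-linked ones, and the labels give no sex.

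In the authors' deposited table, 746 genes had an unadjusted p under 0.05, 436 with a ratio above 1 and 310 below 1. After Benjamini-Hochberg adjustment of those p-values 0 genes stayed under 0.05, with 0.602 as the smallest. The direction of the authors' ratio and of the log2 difference in limma was the same for 97.6% of genes, and 440 genes had an unadjusted p under 0.05 in both, where independent lists of these sizes would share 101. Both come from the same 6 libraries and are not independent.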

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

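Array weights, median-of-ratios scaling, a pseudocount of 1 in the deposited unit, rescaling without small RNA genes, length trend removal and leaving out both libraries numbered 3 were tried only after the results were seen. The counts of genes were 0 higher and 0 lower under each planned setting with all 6 libraries, with 1398 to 1674 genes at an unadjusted p under 0.05, limma without its trend and the replicate block giving those ends. Filters that removed no gene tested nothing. Leaving out a library in turn gave 0 to 786 genes higher and 0 to 531 lower, the upper values without fl/fl replicate 3. Array weights gave 321 and 222, and leaving out replicate 3 of both groups gave 874 and 640; the cause was not tested beyond fewer or down-weighted libraries. The Mpc2 level difference was -0.32 to -1.11 with 1 library left out, past the threshold in no such fit, and -1.30 without replicate 3 of both groups (limma adjusted p = 0.00279, against 0.818 as the highest).

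Camera called 9 to 15 lists with 1 library left out, 11 with a pseudocount of 0.1 and 13 without replicate 3 of both groups, and 0 under each of these and the other settings with an estimated correlation (smallest adjusted p = 0.320); fry, run only in the fit of all 6 libraries, called 0. With the length trend removed the nuclear-encoded respiratory chain was called lower (camera adjusted p = 0.0148, up to 0.782 elsewhere; adjusted p = 0.538 with an estimated correlation). Same-numbered libraries had deviations from their group means correlated at 0.07, -0.04 and -0.07, which gave no sign of pairing by number. This check cannot see what the libraries numbered 3 share if both lie between the groups. Those libraries correlated best with each other (0.980), though not every library correlated best with its own number. The replicate block gave 0 genes and 10 lists, without the ATF4 and macrophage lists (camera adjusted p = 0.0622 and 0.0553). Of 115 named genes other than Mpc2, 100 passed the threshold without fl/fl replicate 3, but this count says little, since the largest changes were named from that fit. Reversals were near 0: Cidea 0.00858 and Xist -0.0206 with array weights; without replicate 3 of both groups Cidea 0.24, Xist -0.18, S100a9 -0.14 and Myh7 0.10. With 1 library left out Cidea ranged from -0.30 to 0.12 and Xist from -0.11 to 0.31. The cause was not tested. Depth ran from 92.9 to 389 (1000000 coverage steps), so low genes of fl/fl replicate 1 are the least precise.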

Other observations

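The genes of this paragraph, and the list of liver genes in it, were chosen after values were seen. The smallest unadjusted p-values of all 6 libraries included genes of no fixed list: Sfrp1, an inhibitor of Wnt signalling, was at 26.6, 29.3 and 56.6 ppm in fl/fl and 142, 92.0 and 84.7 in CS-Mpc2-/-, and Prelp, a matrix proteoglycan, at 21.2, 25.2 and 47.6 against 75.8, 86.5 and 71.2. Igf1, a growth factor, had means of 16.4 ± 3.32 in fl/fl and 36.6 ± 8.05 in CS-Mpc2-/- (SD, n = 3 each), with 15.6 in fl/fl replicate 3, a log2 difference of 1.11 ± 0.24 (SE), so for this gene fl/fl replicate 3 stayed with its group. The vault RNA gene Vaultrc5 was at 125, 184 and 364 against 625, 535 and 770. The limma adjusted p of these 4 genes was 0.220. Of 28 liver genes, 12 are in the table, which lists a gene only if a group mean reached the authors' minimum, so a gene high in 1 library alone enters by that value. This favours such genes and limits what follows from the 10 of the 12 that were highest in CS-Mpc2-/- replicate 1. Among these Alb, the serum albumin, was at 49.8 ppm there and at most 5.36 in the other libraries, and Apob, the main protein of low-density lipoprotein, at 15.2 against at most 0.700. The plasma protein genes Ahsg and Fetub were instead highest in CS-Mpc2-/- replicate 2, at 19.6 and 8.53 ppm against 11.9 and 1.2 in replicate 1. The heart also expresses several of the 12, such as C3 and Trf.

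In what follows, the tests of exchanged labels, of a whole pool with the wrong label, of non-myocyte RNA and of the splits of gene counts were chosen after their results were seen, as were the interval around the ribosomal value and the bound on genes that fell to 25%. Of the 10 splits of the 6 libraries into 3 and 3, 10 gave as many genes as the real one, which called 0 as did the highest other, and 2 gave as many lists, 12 for the real split and 15 for the highest other. That other split exchanges the libraries numbered 3, setting fl/fl replicates 1 and 2 with the library labelled CS-Mpc2-/- replicate 3 against the rest, and gave 1645 genes at an unadjusted p under 0.05 in limma, against 1631 for the real split. The splits are too few to weigh chance.

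The pattern a reader would look at first is fl/fl replicate 3, which stands with the CS-Mpc2-/- libraries in the genes that separate replicates 1 and 2 of the groups (1514 genes). Shallow sequencing would lose the pattern in well-covered genes, where the position of fl/fl replicate 3 was 0.760 on a log2 scale from 0 (fl/fl) to 1 (CS-Mpc2-/-). A pool of 1 heart of each group in equal parts would lie between 0.35 and 0.65 on the linear scale. On it fl/fl replicate 3 lay at 0.673 for higher genes (95% interval 0.646 to 0.691, which does not decide) and at 0.742 for lower genes (0.723 to 0.765). In this library 70 genes that fell to 25% or less had a median of 38.4% of the fl/fl level (35.7 to 42.7), where equal parts keep at least 50%. These intervals are over genes of 1 library, which are not independent, and leave out variation between hearts. Both bounds also take fl/fl replicates 1 and 2, by which these genes were chosen, as the level of any fl/fl heart. The lower genes lay outside both bounds. Mpc2, a single gene, lay at 0.562 on the linear scale, inside 0.35 to 0.65. Equal parts are not excluded. Exchanged labels of the libraries numbered 3 stay open: they would put the one labelled CS-Mpc2-/- near fl/fl, where its median position of 0.712 goes against them, but they would part Mpc2 fully (45.2, 38.9 and 46.3 ppm against 14.9, 18.2 and 27.7, the lowest being 1.40 times the highest), and a fl/fl library near CS-Mpc2-/- remains with either labelling. A pool of CS-Mpc2-/- hearts labelled fl/fl cannot be told apart from fl/fl hearts with disease, since Mpc2 lay at 0.562 of the way and is itself at the fl/fl level in the library labelled CS-Mpc2-/- replicate 3, so either may apply, and unequal parts were not tested.

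The library labelled CS-Mpc2-/- replicate 3 had Mpc2 at the fl/fl level, while over the 1514 genes its median log2 position was 0.712 and its correlation across all genes, which are not independent replicates, was higher with fl/fl replicate 3 (0.980) than with CS-Mpc2-/- replicates 1 and 2 (0.961 and 0.964). Its short-transcript trend would not give this, since the excess of Mpc2 over replicates 1 and 2 (1.44 on the log2 scale) was at percentile 100 of 532 genes of like length. A larger share of non-myocyte RNA, which keeps Mpc2, would raise the markers of those cells, and their median difference was -0.18. A fl/fl heart making up an equal part of the pool would hold positions at or below 0.65. These were 0.592 for higher genes, which allows it, and 0.787 for lower genes, which lies outside. The 70 genes that fell to 25% or less had a median of 38.7% of the fl/fl level (95% interval up to 43.4), below the 50% of equal parts. On the linear scale Mpc2 itself lay at -0.165, beyond fl/fl replicates 1 and 2, whereas equal parts would lie between the groups. That is 1 gene of 1 library and does not decide. The limits given above for the intervals and for the level of a fl/fl heart apply here too, so equal parts are not excluded. A smaller fl/fl share, which would leave Mpc2 lower than equal parts do, was not tested. Exchanged labels stay open here too, and incomplete deletion, or transcription of exons that were not deleted, could each raise whole-gene coverage and were not tested.

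The ribosomal protein list was called higher by camera with a median of 0.42 (adjusted p = 0.466 with an estimated correlation), and the short transcripts of the shallow fl/fl libraries are a candidate explanation. With each library's length trend removed the median was 0.27 (95% interval 0.13 to 0.35) and camera still called the list (adjusted p = 0.00219; adjusted p = 0.392 with an estimated correlation). The interval holds values on both sides of 0.5 of the earlier median, so trend and genotype cannot be told apart here.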
